A study of Mus musculus with 4 samples.

How the data were processed

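RNA and open chromatin were measured in the same nuclei of cultured mouse CD8+ T cells, in 1 WT and 1 Rpa1 cKO sample, giving 4 libraries. Nuclei were made into libraries with the SeekOne DD multi-omics kit and sequenced on a SURFSeq 5000, per the labels. Groups were taken from the sample titles. The submitters' processing notes name Seurat 4.3.0 and the genome build mm39, without a role for either; the aligner, the counter and the peak caller are not given in the sources used here. The RNA values are raw UMI counts per gene and barcode, as deposited. The chromatin values are raw counts per peak and barcode, as deposited, with 91.7% of WT and 91.3% of cKO entries even, so most fragments added both ends. For that reason chromatin intervals were computed on counts divided by 2.

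Peak coordinates were checked against gene ends of the RefSeq annotation of GRCm38. Over 5 chromosomes, 37.5% to 64.2% of protein-coding genes had an end inside a WT peak, against 3.62% to 17.3% after shifting the positions, so coordinates are given as GRCm38 although the notes name mm39. Of 32285 gene IDs in the RNA files, 32158 matched the name table. Older histone and receptor symbols were matched through synonyms. The annotation used here gives no strand, so the planned promoter was replaced by the annotated gene end, start or stop, that had the higher mean accessibility within 1000 bases. No reference genome sequence was used here, so the planned motif comparison was not run.

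Nuclei needed at least 500 genes and under 10% of UMIs from mitochondrial genes, which 11352 WT and 10948 cKO barcodes met. Doublet calls were to be used if at least 0.5% of nuclei over both libraries were marked, which was met. Scrublet, as in scanpy 1.11.5 with an expected rate of 0.08, found no threshold in the WT library and marked 0 nuclei there, so all were kept. In cKO it marked 189 nuclei (1.73%), which were left out. Doublets were thus treated unequally, and both a run with them kept and a run without the 8% highest scores of each library were made. Both libraries were clustered together without integration: 2000 variable genes without receptor, mitochondrial and sex-linked genes, 30 principal components and Leiden resolution 0.6 (leidenalg 0.10.2, seed 0). A cluster was named for a type, from 12 marker sets, where at least 3 of its markers, more than for any other type, were at 10 CPM and 3-fold over all other nuclei, with at least 1 among the 50 leading genes by fold. Remaining clusters were called CD8 T-like where at least 3 CD8 T markers were at 10 CPM and 3-fold over the B-like cluster, with at least 200 nuclei of each library and a median UMI count at least 1/3 of the library's. The rule on leading genes was chosen after seeing that cluster 1, of 5 WT and 112 cKO nuclei led by Dlgap2 and Nrxn3, would have been called gamma-delta on weak markers. Clusters 0, 1 and 4 stayed unnamed, at 1597 WT and 1808 cKO nuclei. Clusters named for a type other than CD8 T were left out, leaving 11000 WT and 9031 cKO nuclei. Their median UMIs were 5763 and 5728, their mitochondrial shares 5.56% and 4.49%, and their median chromatin counts 10593 and 11427.

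UMIs were summed over kept nuclei and scaled to the same total in each library (CPM), and a difference is the log2 ratio of CPM, cKO over WT. With 1 library per genotype no test was run. Ratios have 95% exact conditional binomial intervals, CPM exact Poisson intervals and shares exact Clopper-Pearson intervals, all for counting error only. Genes were counted as higher or lower at 1.5-fold among those at 10 CPM in 1 library. Before the data were examined, 25 gene lists were fixed. Members needed 5 CPM in 1 library and 50 UMIs over both. The percentile of a list's median comes from 10000 random lists of the same size matched on mean expression in 20 bins, and does not depend on the scaling. The interval of a median came from 1000 redraws of the counts. Genes were named by a rule fixed at the same time: the 12 highest and 12 lowest ratios among genes at 20 CPM in 1 library and 100 UMIs in each, without unnamed, receptor segment, mitochondrial, ribosomal protein and Y-linked genes, Xist and Tsix, plus up to 4 members of each list with the largest ratios. Isg15, Irf7 and Eomes are list members named outside that rule, after their values were seen, as were the T-cell receptor alpha locus, Trim16 and markers of other cell types. Some genes that the rule gives are not reported here.

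For cell cycle shares, each nucleus was thinned to 2000 UMIs, shallower nuclei were left out, and a nucleus counted when its S phase or its G2 and M phase UMIs reached the level exceeded by 10% of WT nuclei. Within-cluster ratios were averaged with equal weight over clusters with at least 200 nuclei of each library. Peaks were compared with bedtools 2.31.1. A shared region was a pair of peaks that overlapped by at least 50% of each, and ratios are of counts scaled to all counts in peaks (CPM), at 10 CPM or more in 1 library. Each library's count is that of its own whole peak, while the coordinates given are those of the overlap. A difference in peak width therefore enters the ratio. The 6 highest and 6 lowest regions at 20 CPM were named.

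The alternatives were TMM factors (edgeR 4.0.16 in R 4.3.3) and median-of-ratios factors, no filter on genes and mitochondrial share (clusters of other types and marked doublets still left out), a filter of 1000 genes and 5% mitochondrial UMIs, doublets kept, all clusters kept, other floors, means of per-nucleus CPM, equal cluster weights, Leiden resolution 1.0 and other definitions of overlap and distance. The comparison of ratios was tested on simulated counts with 200 changed genes among 8888. All genes changed 2-fold or 4-fold were found at 1.5-fold, and 0 of 8688 unchanged genes, whose intervals held the true value in 95.0%. Of 100 unchanged lists, 4% fell outside the central 95% of random lists. The simulated counts held counting error only, so differences between animals or libraries of 1 genotype were not covered. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used.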

Results

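The series holds 4 libraries from mouse CD8+ T cells, made with a droplet kit that reads RNA and open chromatin from the same nucleus. Cells came from lymph nodes of wild-type (WT) mice and of mice in which Cre recombinase under Cd4 control acts on loxP-flanked Rpa1 (Rpa1 cKO). Rpa1 encodes the large subunit of replication protein A, which binds single-stranded DNA during replication and repair. Both cultures ran for 18 h on plate-bound anti-CD3 at 1 µg/mL with anti-CD28 at 1 µg/mL, IFN-α at 50 ng/mL and IL-4 at 20 ng/mL, a mixture meant to induce virtual memory T cells. Each genotype had 1 RNA library and 1 chromatin library, so there were no replicates and no test between genotypes, and all intervals cover counting error only. The WT RNA library held 12670 barcodes and 79482368 UMIs, with a median of 5316 UMIs per barcode. The cKO RNA library held 12224 barcodes and 73383898 UMIs, with a median of 4800. The chromatin libraries of the same barcodes held 136465717 counts in peaks for WT and 134385813 for cKO. After filters, 11000 WT and 9031 cKO nuclei were kept, with 74105113 and 61827611 UMIs.

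The first comparison asked whether the targeted transcript differed between the labelled genotypes. Rpa1 (ENSMUSG00000000751, chromosome 11, 75300259 to 75348454, GRCm38) stood at 123 CPM in WT and 109 CPM in cKO, a log2 ratio of −0.18 with a counting interval of −0.22 to −0.13. After thinning to 2000 UMIs per nucleus, 20.3% of WT and 17.2% of cKO nuclei held an Rpa1 UMI, against 44.4% and 39.0% unthinned. In B-like nuclei, where Cd4-driven Cre is not active, the thinned shares were 15.6% of 212 WT and 16.2% of 797 cKO nuclei, with median depths before thinning of 3967 and 3424 UMIs. Within clusters of nuclei the log2 ratio had a mean of −0.38 and ran from −1.15 in cluster 0 to 0.07 in cluster 9, below 0 in 6 of 7. Cluster 0 stayed unnamed and was shallow, at median depths of 1600 WT and 1386 cKO UMIs. Of the other subunits, Rpa2 had a log2 ratio of 0.29 pooled and a mean of 0.01 within clusters, and Rpa3 stood at 4.63 CPM in WT and 4.92 CPM in cKO. The labels do not give the floxed exons, and UMIs from outside the deleted part remain countable, so this is a weak check of the labels.

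The main comparison asked how the transcriptome of the kept nuclei differed between Rpa1 cKO and WT. The genes with the highest ratios included the natural killer receptor genes Klrc1 and Klrc2 and the T-cell receptor delta constant gene Trdc, and those with the lowest included interferon-inducible genes. Of 9091 genes at 10 CPM or more in at least 1 library, 281 were at least 1.5-fold higher and 182 at least 1.5-fold lower in cKO, and 115 and 36 passed 2-fold. Trdc (ENSMUSG00000104876) went from 4.44 to 48.6 CPM, a log2 ratio of 3.45 (3.29 to 3.62). Klrc2 and Klrc1, which encode NKG2 receptors, had log2 ratios of 3.35 and 3.24. The chemokine gene Ccl1 reached 3.19 and Il18r1, a chain of the interleukin-18 receptor, 2.76. The kinase gene Lrrk1 went from 18.9 to 164 CPM and Prelid2 from 20.9 to 172 CPM. The other genes among the 12 highest were Ttc39c at 3.23, Rai14 at 2.94, Tshz3 at 2.88, Gas7 at 2.85 and Tmem163 at 2.77.

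At the other end, Ifi208 (ENSMUSG00000066677) went from 152 to 6.94 CPM, a log2 ratio of −4.45 (−4.59 to −4.31). The 12 lowest held 5 genes of the interferon-inducible Ifi200 family in one stretch of chromosome 1 (173468485 to 173698393, GRCm38), with Ifi209 at −1.60, Ifi214 at −1.41, Ifi206 at −1.18 and Ifi213 at −1.15 beside Ifi208. They also held Oasl2 at −1.40, Oas3 at −1.14 and Ifit1 at −1.11, all induced by type I interferon. Adgrg5 stood at −1.69, Ifngas1 at −1.27, Abcg1, a cholesterol exporter, at −1.20 and Actn2 at −1.11. Counts of near-identical family members (the Ifi200, Klrc and Oas genes) may be split between copies, and Ifngas1 is antisense RNA whose strand was not checked, so these values are uncertain per gene. The split between higher and lower genes depended on the floor and on the scaling. A floor of 50 CPM gave 79 higher and 106 lower. TMM factors, which shift the median of all genes by −0.13 on the log2 scale, gave 186 higher and 320 lower. Median-of-ratios factors, with a shift of −0.16, gave 171 higher and 355 lower.

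**Figure D1:**
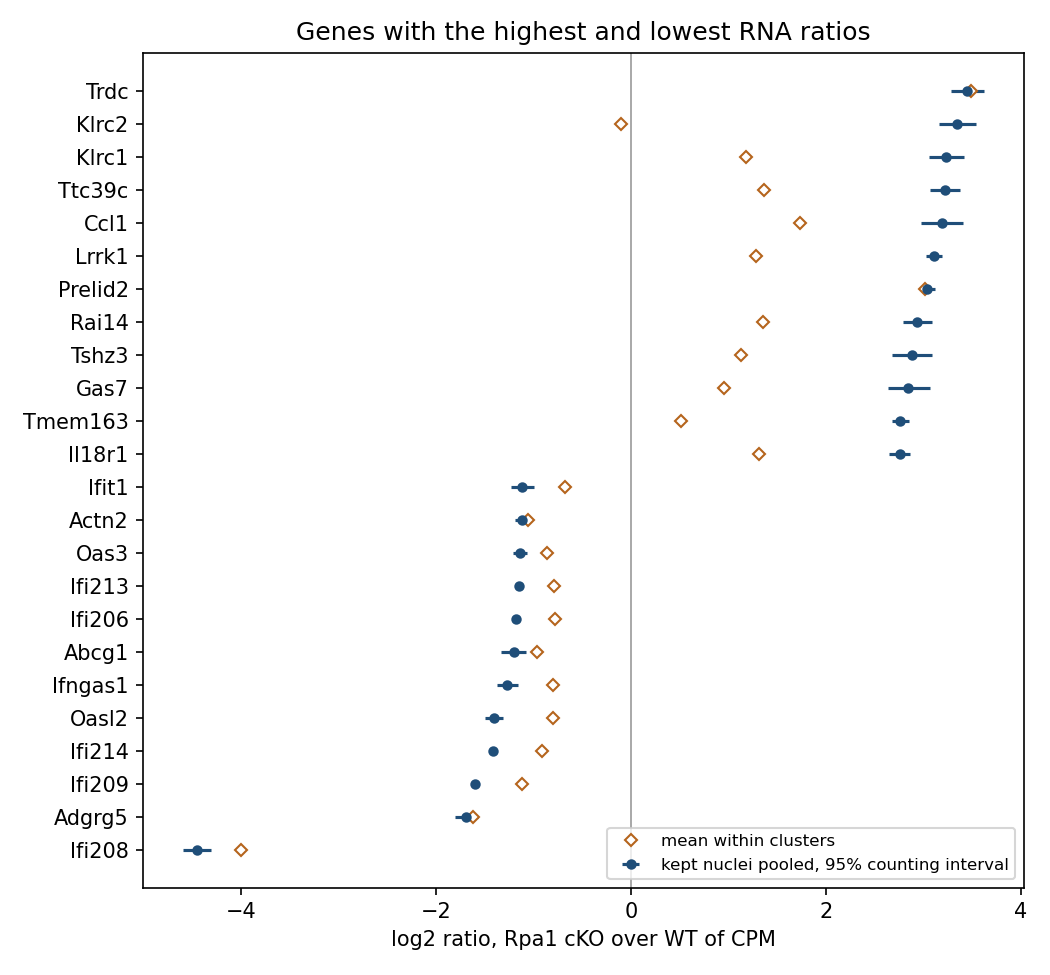
Log2 ratio of CPM, Rpa1 cKO over WT, for the 12 highest and 12 lowest genes under the naming rule, with 95% counting intervals (filled) and the mean over 7 clusters (open). Trdc and Prelid2 keep their ratio within clusters, and the open value of Klrc2 rests on clusters with few of its UMIs, while cluster 9 alone gives 1.42.

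Interferon-stimulated genes formed the list with the lowest median. All 35 measured members were below 0 and 29 of them were at least 1.5-fold lower in cKO, with none higher. The median log2 ratio was −0.89 (−0.91 to −0.83), below all 10000 random lists matched on expression (percentile 0). Isg15, a ubiquitin-like antiviral protein, went from 26.0 to 13.4 CPM, and Irf7 from 48.9 to 25.2 CPM. The cytosolic DNA sensing list, which shares Zbp1 and Ifi203 with this one, had a median of −0.37 at percentile 0, with 3 of 11 members lower and none higher, among them Zbp1 at −1.07 and Samhd1 at −0.63. Samhd1 turned to 0.12 with clusters weighted equally, and the list's mean within clusters was −0.165.

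In the cytotoxic effector list 8 of 17 members were at least 1.5-fold higher in cKO, none were lower by that much and 4 were below 0. Its median was 0.54 (0.51 to 0.64) at percentile 100, with a mean of 0.11 within clusters. Ifng went from 139 to 713 CPM, with 33833 of its 44095 cKO UMIs in cluster 9. Fasl, the death receptor ligand, had a log2 ratio of 2.57, Prdm1 1.88 and Zeb2 1.23. The T-cell receptor activation list had 7 of 27 members higher and none lower past 1.5-fold, 4 below 0, a median of 0.39 at percentile 100 and a mean of 0.12 within clusters, with Batf3 at 1.69, Zbtb32 at 1.22, the chemokine gene Xcl1 at 1.21 and Ccl3 at 0.92. The virtual memory program, the state the culture was meant to induce, had 5 of 16 members higher and 1 lower, and its median of 0.12 (0.09 to 0.19) lay at percentile 91.5. Within it Il18rap was at 2.57, Ccl5 at 2.00, Klrk1 at 1.12 and Cd44 at 0.79, while Eomes, a transcription factor of memory CD8 cells, went from 98.4 to 67.4 CPM. The virtual memory median turned to −0.01 with TMM factors and −0.04 with median-of-ratios factors, which move all genes alike and leave the percentile as it is. It was 0.26 under the filter of 1000 genes and 5% mitochondrial UMIs, 0.25 with all clusters kept and 0.26 at a list floor of 20 CPM.

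The medians of the cell cycle and p53 lists lay above matched random lists in the pooled nuclei. All 40 S phase genes were above 0 and 5 of them at least 1.5-fold higher, with a median of 0.26 (0.25 to 0.29) at percentile 100 and a mean of 0.04 within clusters. E2f7, a repressor of the E2F family, was at 1.24 and Rrm2, a subunit of ribonucleotide reductase, at 0.86. In the G2 and M phase list 1 of 22 members was higher, Birc5 at 0.63, and the median was 0.28 at percentile 100, which turned to −0.11 with clusters weighted equally. Of 24 measured p53 targets 7 were higher and none lower, with a median of 0.32 (0.29 to 0.36) at percentile 100, which fell to 0.14 at a list floor of 20 CPM. The members with the highest ratios were of low expression. Cdkn1a, Psrc1, Pmaip1, Sesn2, Plk2 and Bbc3 reached the floor of 5 CPM in cKO only, so they counted as measured through the library where they were higher. Cdkn1a, which encodes the cell cycle inhibitor p21, went from 1.09 to 5.03 CPM, Psrc1 was at 2.02, Pmaip1, which encodes the cell death protein Noxa, at 1.12 and Sesn2 at 1.10. The ATR and repair list had no member past 1.5-fold, a median of 0.12 and percentile 98.9, with Fancd2 at 0.56 and Atm at −0.40; its median turned to −0.01 with TMM factors.

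Transcripts of the mitochondrial genome were below 0 for all 13 members, none past 1.5-fold, with a median of −0.25 at percentile 0.06 and mt-Nd3 at −0.48. Left-out types gave −0.29 in B-like, −0.46 in dendritic-like, −0.22 in gamma-delta T-like and 0.22 in CD4 T-like nuclei, and the filter on nuclei acts on these transcripts. Cholesterol synthesis had a median of −0.19 at percentile 0, with 15 of 18 members below 0 and Mvd at −0.42. Naive and quiescence genes had 4 of 24 members lower and none higher, with a median of −0.08 at percentile 0.33 and Ms4a4b at −0.89. Its sign turned with clusters weighted equally, to 0.10, and the mean within clusters was 0.02. The IL-2 and STAT5 list had 2 of 12 members higher, a median of 0.20 and percentile 99.8, with Il2ra at 0.72 and Il2 at −0.52. Unfolded protein and stress genes had a median of 0.25 at percentile 99.95 (1 of 14 higher, Asns at 1.76), and glycolysis 0.17 at percentile 99.9, with no member past 1.5-fold. Ribosome biogenesis had a median of 0.16 at percentile 99.98, with no member past 1.5-fold and Nolc1 at 0.28. For IL-4 response the median was 0.18 at percentile 95.4, with 2 of 9 higher and 1 lower, Ahr at 1.24 and Il4ra at −0.64. For inhibitory receptors it was 0.16 at percentile 96.7, with 3 of 12 higher, among them Entpd1 at 2.04 and Havcr2 at 1.72. Oxidative phosphorylation (0.13, percentile 94.9), histones (0.15, percentile 83.6), chromatin regulators (0.06, percentile 78.1), migration receptors (0.02, percentile 25.1) and cell death genes (0.0013, percentile 11.9) did not stand apart. With TMM or median-of-ratios factors the medians of oxidative phosphorylation, cell death, migration receptors and chromatin regulators turned negative. Those of inhibitory receptors, ribosome biogenesis and histones did so with median-of-ratios factors only. The RPA list and the sex-linked list had 2 measured members each and no median, and Xist was present in both libraries, at 968 and 1244 CPM.

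**Figure D2:**
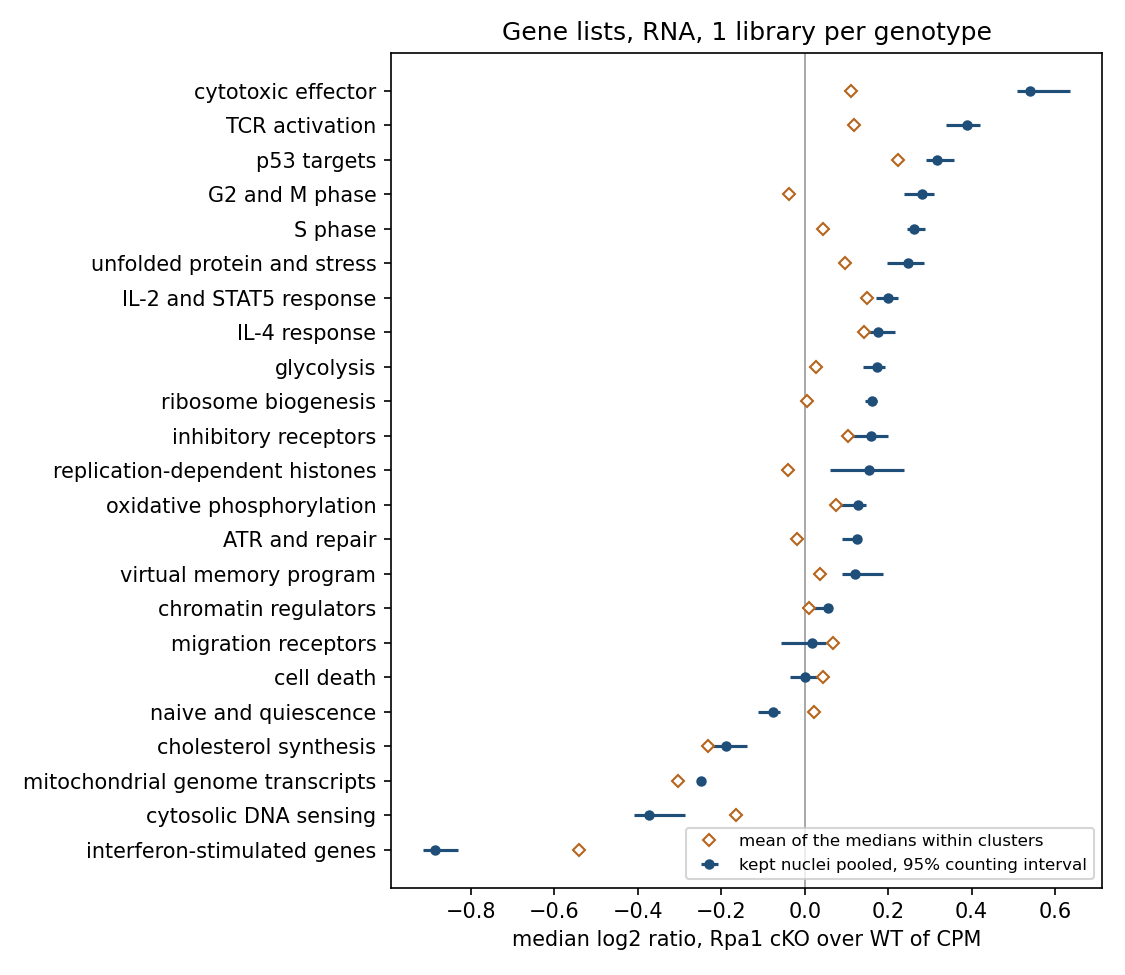
Median log2 ratio of each gene list, Rpa1 cKO over WT, pooled over kept nuclei with 95% counting intervals (filled), and the mean of the medians over clusters (open). Interferon-stimulated genes have the lowest median at −0.89, and the cytotoxic effector list moves from 0.54 pooled to 0.11 within clusters.

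The next comparison asked how nuclei were distributed over cell types and cell cycle. CD8 T-like nuclei made up 82.8% (82.1 to 83.5) of 11352 WT and 67.1% (66.2 to 68.0) of 10759 cKO nuclei. Types that an isolation of CD8+ T cells should remove were more frequent in the cKO library. B-like nuclei made up 2.16% of WT and 9.16% of cKO nuclei, and gamma-delta T-like nuclei 0.423% and 4.68%. CD4 T-like nuclei made up 0.317% and 1.18%, and dendritic-like nuclei 0.203% and 1.03%. The isolation and the handling of each culture can set these shares. Among kept nuclei, markers of other types also differed: Cd4 stood at 1.12 and 6.08 CPM, the gamma-delta gene Tcrg-C2 at 0.540 and 9.35 CPM, and the B cell gene Pax5 at 1.81 and 5.21 CPM. Whether the Cd4-driven Cre construct of the cKO animals adds to Cd4 RNA was not tested. Markers of 1 type did not move together: the B cell genes Ighm (61.5 and 41.6 CPM) and Ighd (14.1 and 9.04 CPM) were lower in cKO, and Cd79a had a log2 ratio of 0.04. The natural killer gene Klre1 was at 2.45. Among clusters of CD8 T-like nuclei, the highest ratio of shares was that of cluster 9, led by Mybpc1, Il18rap, Lrrk1, Klrc2 and Ifng, with 2.31% of WT and 16.9% of cKO nuclei. Trac and Cd3g were not among the CD8 T markers that met the naming rule in cluster 9, and Trac was not in cluster 3 either. Cluster 9 had the highest median depths of these clusters, 10792 WT and 9453 cKO UMIs, and 87.4% of it came from the cKO library. Its defining genes are among the genes that differ most between the libraries, so its size and those ratios are one observation. Cluster 3 went from 28.1% to 13.4%, and cluster 6, led by genes that include the interferon-inducible Ifit3 and Oas2, from 19.5% to 8.01%, with the same limit for cluster 6. At 2000 UMIs per nucleus, 9.18% of WT and 14.5% of cKO nuclei reached the S phase level of 12 UMIs, against 1.42% and 1.00% of B-like nuclei and 9.74% and 14.8% of kept nuclei unthinned. The G2 and M phase level of 4 UMIs was reached by 8.78% and 12.6%, against 4.72% and 1.51% of B-like nuclei and 9.65% and 13.8% unthinned. Thinning left out 1398 WT and 1595 cKO nuclei, and free RNA can add to such levels.

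The comparison within clusters asked how much of the difference remained inside groups of similar nuclei. Over the 7 clusters with at least 200 nuclei of each library, weighted equally, 145 of the 9091 genes were at least 1.5-fold higher and 100 lower. Of the 281 pooled higher genes 122 were among them, and of the 182 lower genes 75. All 12 lowest genes stayed at least 1.5-fold lower in this mean, Ifi208 at −4.00 and Adgrg5 at −1.62, and 11 of them were below 0 in every one of the 7 clusters, Ifi213 being the exception. Of the 12 highest genes 10 stayed at least 1.5-fold higher, led by Trdc at 3.49 and Prelid2 at 3.02, while Tmem163 stood at 0.51. The mean of Klrc2, −0.10, rests on clusters with few of its UMIs, down to 0 in one library; in cluster 9, with 2055 of its 2143 cKO UMIs, the ratio was 1.42 (1.15 to 1.70). Cdkn1a at 1.73, Psrc1 at 1.76, Ahr at 1.22 and Ifng at 1.41 were above 0 in all 7. Cdkn1a and Psrc1 had 81 and 120 WT UMIs over all kept nuclei, so their signs in single clusters are uncertain. Klrk1 went from 1.12 pooled to a mean of −1.16, below 0 in 5 of 7 clusters, but stood at 0.34 in cluster 9, with 2450 of its cKO UMIs.

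Among lists, the mean of the within-cluster medians was −0.54 for interferon-stimulated genes, with a range from −0.92 to −0.07. It was 0.22 for p53 targets (0.08 to 0.45) and −0.30 for mitochondrial genome transcripts (−0.46 to −0.16). The cytotoxic effector list fell to 0.11 (−0.11 to 0.75), S phase to 0.04, G2 and M phase to −0.04 and virtual memory to 0.04. Unfolded protein and stress fell to 0.10, glycolysis to 0.03, ribosome biogenesis to 0.0046 and ATR and repair to −0.02. The unnamed clusters 0 and 4 count among the 7, with median depths of 1386 to 1600 UMIs. Cluster 4 gave the −0.92, and cluster 0 the 0.45 and 0.75. Clusters were made from both libraries together without integration, and genes that differ between genotypes helped to define them, so these means can remove part of a genotype difference.

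**Figure D3:**
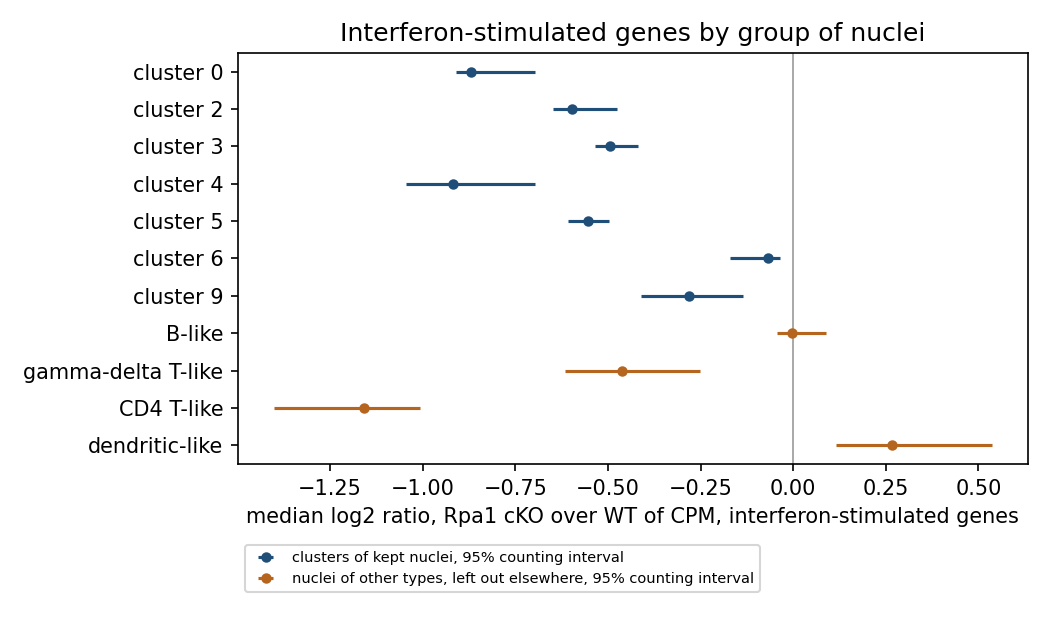
Median log2 ratio of interferon-stimulated genes, Rpa1 cKO over WT, by group of nuclei, with 95% counting intervals. Kept clusters lie between −0.92 and −0.07, B-like nuclei at −0.0023, dendritic-like at 0.27, gamma-delta T-like at −0.46 and CD4 T-like nuclei at −1.16.

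The chromatin comparison first asked how far the peaks of the libraries overlapped. The WT library had 88630 peaks over 78.9 Mb and the cKO library 95269 peaks over 84.1 Mb. Of the WT peaks 93.4% (93.2 to 93.6) overlapped a cKO peak, and of the cKO peaks 86.8% (86.6 to 87.0) overlapped a WT peak. Peaks were called per library, so a peak missing from one list is not a region without accessibility.

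Accessibility was then compared over 81495 regions shared by both peak lists, of which 24812 had 10 CPM or more, relative to all counts in peaks, in at least 1 library. Counts are those of each library's own peak, so a difference in peak width enters the ratio. The cKO library was at least 1.5-fold higher in 674 regions and lower in 336, with a median log2 ratio of −0.04. Of 10283 regions compared at gene ends, 66 were higher and 39 lower. Of 8669 in gene bodies these numbers were 312 and 182, and of 5860 intergenic regions 296 and 115. A region inside Cd4 (chromosome 6, 124884917 to 124886572, GRCm38) went from 21.5 to 90.7 CPM, 4.23-fold higher. The cKO animals carry Cre under Cd4 control, and whether that construct adds counts here was not tested. Inside Prelid2, a region of chromosome 18 (41887858 to 41889033) was 5.90-fold higher and another (41921871 to 41923252) 2.73-fold higher. Regions inside Ciapin1 (chromosome 8, 94827759 to 94828713) and Nsmce2 (chromosome 15, 59585842 to 59586757) were 3.84-fold and 2.72-fold higher. The highest ratio, 41.4, was at an intergenic region of chromosome 1 (24612372 to 24613139), from 180 counts in WT to 6443 in cKO, where the genome carries a copy of mitochondrial DNA, so its reads are uncertain.

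The lowest ratios lay near Gstp3 (chromosome 19, 4060148 to 4061546), a glutathione transferase gene, at a log2 ratio of −2.15, and in Spink13 (chromosome 18, 62726464 to 62727315) at −1.90. Next came the gene ends of Cnppd1 (chromosome 1, 75140767 to 75142173) at −1.32 and Ifi208 (chromosome 1, 173673408 to 173674369) at −1.29. A region inside Amz2 (chromosome 11, 109432208 to 109433201) was at −1.28 and the gene end of Cacnb1 (chromosome 11, 98019985 to 98021091) at −1.26.

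The last comparison asked whether genes that differed in RNA differed the same way in accessibility at their ends. Across 8133 genes the Spearman correlation of the 2 log2 ratios was 0.31; genes are not independent replicates. Of 374 genes past 1.5-fold in RNA, 313 (83.7%) had the same direction at the gene end. Tshz3 had a gene end ratio of 2.47, Havcr2 0.82, Lrrk1 0.59, Prelid2 0.52 and Ifng 0.49, and Ifi213 −0.78, Ifi206 −0.62, Ifi209 −0.57 and Ifit1 −0.43. Il18r1 and Adgrg5 stood at 0.02 and −0.04 there, despite RNA ratios of 2.76 and −1.69. Over the 33 interferon-stimulated genes with a value the median was −0.23 (−0.26 to −0.19) at percentile 0 among matched random lists, and over 27 T-cell receptor activation genes it was 0.12 at percentile 100. The p53 targets (−0.05, percentile 47.4) and S phase genes (−0.06, percentile 41.2) did not stand apart. Cytosolic DNA sensing, at percentile 0 in RNA, was at percentile 34.9 here, and naive and quiescence, at percentile 0.33 in RNA, was at percentile 99.1 with a median of −0.0061.

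**Figure D4:**
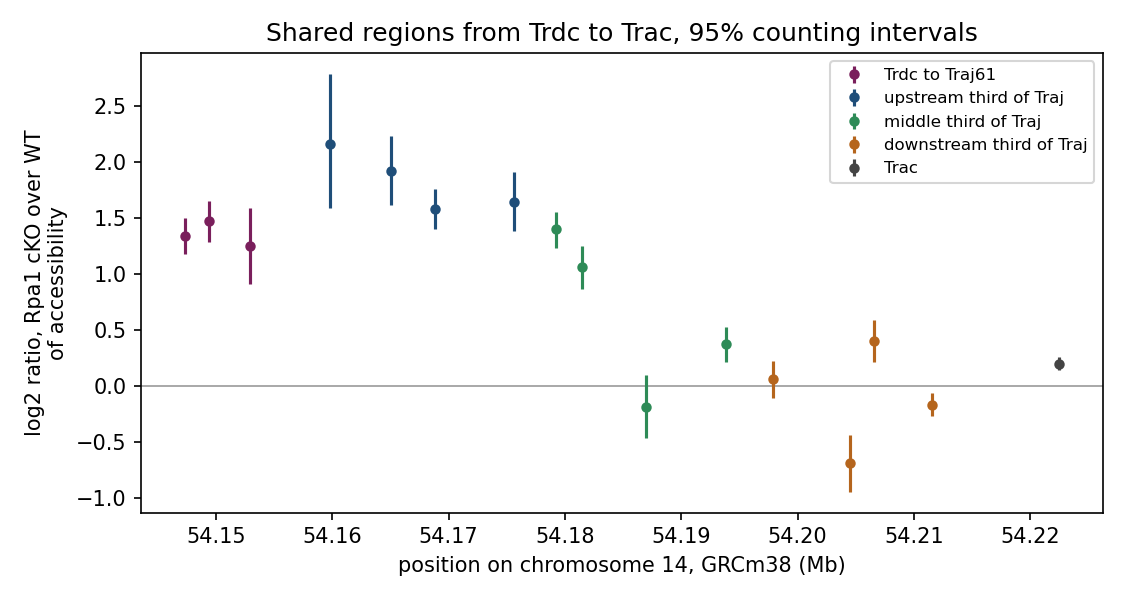
Log2 ratio of accessibility, Rpa1 cKO over WT, of the 16 shared regions from Trdc to Trac on chromosome 14 (GRCm38), against position in Mb, with 95% counting intervals. Summed ratios fall from 1.69 in the upstream joining segments over 0.81 in the middle to −0.08 in the downstream ones.

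Along the T-cell receptor alpha locus, chosen after its values were seen, accessibility differed by position. Between Trdc and the first joining segment the summed log2 ratio was 1.38 (1.27 to 1.49), over the upstream joining segments 1.69 (1.56 to 1.82), over the middle ones 0.81 (0.73 to 0.90) and over the downstream ones −0.08 (−0.15 to −0.0043). The region of the constant gene Trac stood at 0.20. The order upstream, middle, downstream held in each of the CD8 T-like clusters 2, 3, 5, 6 and 9.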

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

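The tests of accessibility at interferon-stimulated genes, of the gamma-delta share and of joining segment RNA were set before their results were seen; the other tests in this part were chosen after. The virtual memory list had a median log2 ratio of 0.20 (0.05 to 0.24) in cluster 2 and −0.23 (−0.31 to −0.08) in cluster 6, and the S phase list 0.13 (0.10 to 0.16) in cluster 3 and −0.11 (−0.18 to −0.04) in cluster 6; these were picked out because the signs are opposite, and the differences themselves were not tested. Nuclei of types left out of the comparisons were picked out because they lie above a count of 0 in cultures of CD8+ T cells. B-like nuclei made up 2.16% (1.90 to 2.44) of WT and 9.16% (8.63 to 9.73) of cKO nuclei. Gamma-delta T-like nuclei made up 0.423% (0.312 to 0.560) and 4.68% (4.29 to 5.10), CD4 T-like nuclei 0.317% (0.222 to 0.439) and 1.18% (0.985 to 1.40), and dendritic-like nuclei 0.203% (0.129 to 0.304) and 1.03% (0.850 to 1.24).

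Interferon-stimulated genes were lower in the cKO library, with a median of −0.89. A weaker interferon signal in the whole culture was argued against by B-like nuclei, which shared it, at −0.0023 (−0.04 to 0.09). Dendritic-like nuclei, only 23 of them WT, went the same way at 0.27 (0.12 to 0.54). Gamma-delta T-like nuclei, 48 of them WT, stood at −0.46 (−0.62 to −0.25), which goes with a weaker signal. The left-out types thus disagree, and a weaker signal was not excluded for all of them. CD4 T-like nuclei, which Cd4-driven Cre also reaches, stood at −1.16 (−1.40 to −1.01), with 36 WT nuclei. A shift between clusters as the whole cause was argued against by the median with clusters weighted equally, −0.44 (−0.46 to −0.35), though it is smaller, and cluster 6, led partly by such genes, went from 19.5% of WT to 8.01% of cKO nuclei, so a shift may account for part. Lower activity of the genes in T nuclei is consistent with their gene ends in CD8 T-like nuclei, with a median accessibility ratio of −0.23 (−0.27 to −0.20, percentile 0), a value that was −0.01 at percentile 54.2 in B-like nuclei. Whether this goes with the genotype, the animal or the isolation cannot be decided with 1 library each.

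Trdc and the upstream joining segments of the T-cell receptor alpha locus were higher in the cKO library. Nuclei like those of the gamma-delta T-like cluster, left among the kept ones, were argued against as the whole source of Trdc. At that cluster's levels, Trdc would need a share of 24.5% of kept cKO nuclei. Other gamma-delta genes gave 1.96% to 8.93%, a ratio of 0.209 for their median. A part was not excluded: Tcrg-C1 and Tcrg-C2 had log2 ratios of 4.62 and 4.11 in kept nuclei, while Il23r was at −0.64. Gamma-delta nuclei with other levels of these genes were not tested. The downstream segments and Trac had a median of 0.059 (single regions from −0.69 to 0.40), so counts were not higher over the whole locus. These regions had been seen when the pattern was chosen, so their median restates it and is no separate test. Joining of variable to joining segments removes the DNA between them, Trdc included, so fewer rounds of rearrangement may leave upstream segments in place. The joining segment RNA test gave a correlation of −1 over only 2 segments, which decides nothing, so the explanation cannot be told apart from others there. Over 59 variable segments, a test taken up after its value was known, the correlation of the RNA ratio with position was 0.63 (0.59 in CD8 T-like nuclei alone), in the direction fewer rounds would give, as a hypothesis. The highest ratios were of Trav13-4-dv7 at 2.70, Trav21-dv12 at 2.05 and Trav15-2-dv6-2 at 1.71, all also named as delta variable segments. Other segments so named went down to −2.02, for Trav14d-3-dv8. Whether delta chain RNA adds to the correlation was not tested.

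Ifi208, Prelid2 and Trim16 differed between the libraries in kept and in B-like nuclei; Trim16 was singled out after its values were seen. In B-like nuclei Ifi208 went from 159 to 10.6 CPM, Prelid2 from 13.9 to 90.2 CPM, and Trim16 from 0 to 24 UMIs, with a lower counting bound of 0.94 for its log2 ratio. Prelid2 had a log2 ratio of 2.70 (2.00 to 3.50) in B-like nuclei. That value cannot decide on loss of Rpa1 acting within T cells, since the 3 genes were chosen for differing there. For Prelid2, T-cell RNA in the droplets of B-like nuclei was argued against. Its level there, relative to kept nuclei, was 3.19 times that of Cd8b1, the highest of 4 T-cell genes. A strain or passenger variant carried by the cKO animals was not decided and cannot be told apart from other differences between the animals, since the 3 genes were chosen for differing in both groups of nuclei. Parents and strain background are not in the labels and were not tested.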

How the results depend on the processing

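The runs with only CD8 T-like clusters and without the 8% highest doublet scores were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because each genotype has 1 library. The motif comparison and its 2 alternatives were not run, since no genome sequence was used here. A value was taken as kept when it stayed inside its counting interval, and a number of genes or regions when it stayed within 1.5 times; the cause of a shift was not tested except where stated. The runs without a filter on genes and mitochondrial share, with doublets kept and with the 2 added sets of nuclei kept Rpa1, the numbers of genes, and the virtual memory, interferon, cytotoxic effector, S phase and p53 lists in that sense. Scaling factors move all genes alike: TMM factors gave Rpa1 −0.31, 186 genes higher and 320 lower, virtual memory −0.011, interferon-stimulated genes −1.02, cytotoxic effector 0.41, S phase 0.13, p53 targets 0.18 and ATR and repair −0.0072. Median-of-ratios factors gave 171 higher and 355 lower, virtual memory −0.041, interferon-stimulated genes −1.05, cytotoxic effector 0.38, S phase 0.10, p53 targets 0.15, ATR and repair −0.037 and ribosome biogenesis −0.00056. With these factors the share of differing genes that were higher went from 60.7% to 36.8% and 32.5%. The filter of 1000 genes and 5% mitochondrial UMIs gave Rpa1 −0.24, virtual memory 0.26, interferon-stimulated genes −0.92, cytotoxic effector 0.48, S phase 0.32 and p53 targets 0.28. All clusters kept gave 121 genes lower, virtual memory 0.25, interferon-stimulated genes −0.62, S phase 0.18 and p53 targets 0.25. Means of per-nucleus CPM gave interferon-stimulated genes −0.72. Equal cluster weights gave 166 higher and 54 lower, virtual memory 0.026, interferon-stimulated genes −0.44, cytotoxic effector 0.062, S phase 0.075 and p53 targets 0.24. They turned naive and quiescence to 0.10, G2 and M phase to −0.11, Klrk1 to −0.10 and Samhd1 to 0.12. A floor of 50 CPM gave 79 higher and 106 lower, from fewer genes compared, and a list floor of 20 CPM gave virtual memory 0.26 and p53 targets 0.14. Interferon-stimulated genes, the cytotoxic effector list, the S phase list and p53 targets kept their sign in all alternatives run, while virtual memory did not. Among shares of nuclei by cluster and by cell cycle, cluster 9 share ratio, cKO over WT and 7.33 as reported, was 5.15 at Leiden resolution 1.0 and 9.03 under the filter of 1000 genes. Among shares of nuclei by cluster and by cell cycle, B-like share ratio (4.25 as reported) was 3.48 under that filter, and the S phase share ratio (1.58 as reported) was 1.44 at the 25% level. Peak overlap was 91.95% of WT and 85.5% of cKO peaks with reciprocal overlap, and 95.5% and 88.9% over peaks seen in 1% of nuclei. A floor of 20 CPM in chromatin left 139 regions higher and 96 lower, from fewer regions, and gene ends within 5000 bases gave a correlation of 0.34. Numbers of genes within clusters kept in both alternatives (143 higher and 77 lower at resolution 1.0, 109 and 129 with TMM factors), as did numbers of regions with merged peaks, TMM factors or all barcodes. Over the 18 other lists, 118 alternative values stayed within their interval, 75 left it without a turn of sign for a called value, and 5 turned as given above. Over 114 named genes these numbers were 718, 420 and 2. A list was called when it lay outside the central 95% of random lists, and a named gene when it passed 1.5-fold. Turns of values not called, such as cell death genes and Rpa3 with TMM factors, are not among the 5 and the 2. Depth limits list members with few UMIs, down to 50 over both libraries, and B-like WT values, which rest on 245 nuclei.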
